A study of Mus musculus with 6 samples.

How the data were processed

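RNA from sorted mouse adipocytes was measured on oligonucleotide arrays, 1 array per sample, with 6 arrays in 3 groups of 2. Bone marrow-derived adipocytes came from the adipocyte fraction of gonadal fat of mice that had received a marrow transplant, and they carried a donor marker: green fluorescent protein (GFP) in replicate 1 and beta-galactosidase (LacZ) in replicate 2. The other groups were gonadal white adipocytes and brown adipocytes from the fat between the shoulder blades. Per the labels' protocols, tissue was digested with collagenase, floating adipocytes were recovered, about 5000 cells were sorted into lysis buffer at a time, and at least 6 sorts were pooled per sample. The RNA was then amplified and labelled with biotin, per the labels' protocols. Pooling averages over sorts, and amplification of small amounts of RNA adds spread that 2 arrays per group can only partly measure. The labels call the samples biological replicates but do not say that they came from separate animals, so p-values measure the spread between these samples, which may in part be technical. The labels used here do not give the sex, age or strain of donors or hosts.

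The deposited values are log2 expression values per probe set, 1 column per array, not pooled. Robust Multi-array Average (RMA) and Partek are named in the submitters' processing notes, with no version, role or order. RMA subtracts background, equalizes the distributions of the arrays and summarizes the probes of a probe set on the log2 scale. The log base is not written in the deposited table and was taken from the values, which run from 1.67 to 14.0 with array medians from 5.46 to 5.72. RMA gives no detection calls. Values near 2 to 3.5 lie near background, and values near 13 to 14 near the upper end of each array, so differences that reach either end understate the true fold. The number of arrays limits the precision.

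The table held 43057 probe sets, of which 33565 had 1 gene symbol in the platform annotation, 857 had several and 8635 were unnamed here. Of the named probe sets, 33376 matched the RefSeq gene table (assembly GRCm38.p6, used for names) by gene ID, and 0 symbols needed an update. Probe sets with several symbols named no gene. For each of 17720 genes, the probe set with the highest mean over all arrays was used. Of 8651 genes with several probe sets, 64, 27 and 2 had probe sets called in opposite directions in the comparisons of bone marrow-derived with white, bone marrow-derived with brown and white with brown, and 0 of them are genes named by the rule stated here. Control probe sets were not analysed here, so the planned comparison of the 3 prime and 5 prime ends of control transcripts has no value. Members of the gene lists without a measured probe set were not analysed here either.

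Group means of all 6 arrays were fitted in 1 linear model per gene with limma 3.58.1 in R 4.3.3, followed by contrasts and empirical Bayes moderation with 3 residual and 2.35 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. An adjusted p in the text is from limma, and a value after ± beside a log2 difference is limma's standard error (SE) with n = 2 arrays per group. A total of 26 gene lists, fixed before the data were examined, was tested with limma's camera at its preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists of a comparison. The lists covered adipocyte identity, brown and white adipocyte genes, adipokines, lipogenesis, fatty acid oxidation, peroxisomes, the respiratory chain, the tricarboxylic acid cycle, mitochondrial biogenesis, glycolysis, inflammatory mediators, Hox genes, cell cycle, immediate early and heat shock genes, and markers of macrophages, neutrophils, T and NK cells, B cells, erythroid cells, hematopoietic progenitors, endothelium, fibroblasts, smooth muscle, skeletal muscle and mesothelium. Camera was repeated with a correlation estimated from the arrays, and fry tested each list by itself. With the estimated correlation camera called 0 lists in every comparison. At an unadjusted p under 0.05 it gave 1 list for bone marrow-derived against white, 2 for bone marrow-derived against brown and 3 for white against brown. The preset test called 13, 17 and 17 of the lists in these comparisons and fry called 11, 8 and 11.

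Genes named in the text follow a rule fixed before the data were examined. It takes the 8 called genes with the largest difference in each direction whose arrays did not overlap (unnamed transcript models passed over), up to 3 called members of each list by size of difference (or the member with the largest difference, as a value), and in every comparison Adipoq, Lep, Pparg, Ucp1, Ppargc1a, Ptprc, Csf1r, Adgre1 and Cd68. Some genes of lists that did not move are left out, and genes named outside the rule are said to be chosen after their values were seen. The similarity of arrays was described by Pearson correlation across genes and by the root mean square of the log2 differences, without a test. Genes shared by both comparisons of the bone marrow-derived arrays were set against independent lists and against 50 simulated data sets of unchanged groups.

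The fit was tested on simulated arrays with the real genes' means and spreads and 200 changed genes of 17720. For bone marrow-derived against white it called 14%, 70%, 92% and 90% of the genes changed by 1, 2, 3 and 4 on the log2 scale, and 6.90% of its calls were unchanged genes. For bone marrow-derived against brown the shares were 10%, 82%, 96% and 98% with 6.41% of calls unchanged, and for white against brown 10%, 76%, 96% and 100% with 9.49%. The simulation changed far fewer genes than limma called in the data, where 25.8%, 20.4% and 9.21% were called in these comparisons. It also drew genes independently and gave every group the same spread, so these shares need not hold for the data. Alternatives were a replicate block, only the 4 arrays compared, other moderation or none, array weights, a filter on dim genes at the 40th percentile, another choice of probe set, a 2-fold minimum, cyclic loess, median centring, and leaving out each array in turn. A macrophage covariate, median centring for the gene lists, a different bone marrow-derived array in each comparison for the shared genes and a second endothelial list were added after seeing the data.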

Results

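The arrays compared adipocytes that descend from transplanted bone marrow with white adipocytes and with brown adipocytes. Marrow-derived and white adipocytes both came from gonadal fat. The labels do not give the sex of donors or hosts, so that fat may not have come from mice of the same sex. There were 2 arrays per group, and the bone marrow-derived pair came from donors with different markers, GFP and LacZ. The comparisons ask how the marrow-derived cells differ in expression from conventional white and brown fat cells. White and brown adipocytes were also compared with each other, which sets the scale of a difference between adipocyte types.

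On average the bone marrow-derived arrays lay farther from white and brown arrays than those lay from each other. The root mean square log2 difference was 0.77 within the bone marrow-derived pair, 0.59 within the white pair and 0.40 within the brown pair. Between groups it averaged 1.25 ± 0.15 (SD over 4 pairs of arrays) for bone marrow-derived against white, 1.16 ± 0.05 (4 pairs) for bone marrow-derived against brown and 1.03 ± 0.04 (4 pairs) for white against brown. Across genes, which are not independent replicates, the GFP and LacZ arrays correlated at a Pearson r of 0.969, and each bone marrow-derived array correlated with white and brown arrays at 0.895 to 0.941. White and brown arrays correlated with each other at 0.9405 to 0.9492, so the ranges overlap. The GFP array lay 1.05 from white replicate 1, as far as that array lay from either brown array (1.05 each).

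Bone marrow-derived arrays had lower values than white arrays for genes of fat oxidation and the white adipocyte program, and higher values for endothelial and Hox genes. For the oxidation genes, a lower share of adipocyte RNA could not be told from lower expression per adipocyte. Sex could not be told from cell type in this comparison. Leptin (Lep), the satiety hormone of white fat, was 6.36-fold lower (log2 difference -2.67 ± 0.21, adjusted p = 0.00358). Bcat1, a cytosolic enzyme of branched-chain amino acid breakdown, was 133-fold lower (-7.06 ± 0.53, adjusted p = 0.00353). The general adipocyte genes Adipoq (adiponectin, -0.95 ± 0.30, adjusted p = 0.072) and Pparg (the master regulator of adipogenesis, -0.13 ± 0.20, adjusted p = 0.689) did not pass the test. Their log2 values in the bone marrow-derived arrays were 12.28 ± 0.59 (SD, n = 2) and 11.69 ± 0.17 (SD, n = 2). In all, limma called 2170 genes higher and 2409 lower in bone marrow-derived adipocytes out of 17720, of which 1696 and 1814 differed at least 2-fold.

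Peroxisomal genes were lower as a group. Of 28 measured members of the peroxisome list 21 were lower and 0 higher, or 25 lower when adjusted over the list alone, with a median log2 difference of -1.06 (camera adjusted p = 5.07e-09, but adjusted p = 0.556 with an estimated correlation). The largest differences were in Acaa1b, a peroxisomal thiolase (-3.98 ± 0.51, adjusted p = 0.00736), Abcd2, a transporter of very long-chain fatty acids (-3.89 ± 0.56, adjusted p = 0.00942), and Gnpat, which starts ether lipid synthesis (-2.65 ± 0.18, adjusted p = 0.00353). Mitochondrial fatty acid oxidation followed, with 12 of 19 members lower and 0 higher (15 lower when adjusted over the list alone), a median of -1.21 and a camera adjusted p = 4.20e-06 (adjusted p = 0.556 with an estimated correlation). Cpt2, of the carnitine shuttle, was 3.66-fold lower (-1.87 ± 0.33, adjusted p = 0.0151), and the matrix enzymes Acadm and Echs1 differed by -1.76 ± 0.25 and -1.69 ± 0.25. In the tricarboxylic acid cycle 10 of 15 members were lower (15 when adjusted over the list alone), with a median of -0.88 (camera adjusted p = 6.70e-06, adjusted p = 0.556 with an estimated correlation). The largest differences were in Idh3a (-1.87 ± 0.17), Dlat (-1.48 ± 0.21) and Dld (-1.45 ± 0.19). The respiratory chain shifted less: 14 of 50 members were lower and 1, Cox7c, was higher (1.17), while 25 lower and 1 higher passed when adjusted over the list alone. Its median was -0.49 (camera adjusted p = 6.70e-06, adjusted p = 0.556 with an estimated correlation), with Uqcrq (-1.33 ± 0.23), Ndufa10 (-1.24 ± 0.17) and Uqcrfs1 (-1.21 ± 0.21) lowest. Ppargc1a, a coactivator that drives mitochondrial gene expression, was 9.94-fold lower (-3.31 ± 0.47, adjusted p = 0.00907). The list of mitochondrial biogenesis regulators it belongs to had 6 of 18 members lower, among them Sirt3 (-1.52 ± 0.20) and Tfb1m (-1.49 ± 0.18), and did not pass as a list (camera adjusted p = 0.0699). Adjusted over the list alone, 2 of its members were higher and 7 lower.

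Lipid storage and secretion genes were lower too. The lipogenesis list had 7 of 20 members lower and 0 higher (9 lower when adjusted over the list alone) with a median of -1.54 (camera adjusted p = 0.00139, adjusted p = 0.556 with an estimated correlation). They included Mlxipl, the carbohydrate-responsive regulator of lipogenesis (-3.22 ± 0.60), the citrate carrier Slc25a1 (-2.59 ± 0.50) and Dgat2, which makes triglyceride (-2.26 ± 0.42). Adipokines were lower in 7 of 11 members and higher in 1, Apln (2.51), with a median of -1.34 (8 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.00181, adjusted p = 0.556 with an estimated correlation). Sfrp5, a secreted Wnt inhibitor, was 42.2-fold lower (-5.40 ± 0.47), Nrg4 14.5-fold lower (-3.86 ± 0.67) and Agt, angiotensinogen, 11.7-fold lower (-3.55 ± 0.71). Of 12 white adipocyte genes 8 were lower and 1, Hoxc10, was higher (3.94 ± 0.35), with a median of -1.85 (2 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.00947, adjusted p = 0.556 with an estimated correlation). The imprinted gene Nnat was 13.9-fold lower (-3.79 ± 0.38). Of 15 adipocyte identity genes 6 were lower (10 when adjusted over the list alone) and 0 higher, with a median of -1.34 (camera adjusted p = 0.00402, adjusted p = 0.556 with an estimated correlation). These were led by the retinol carrier Rbp4 (-2.72 ± 0.62), Gpd1 (-2.69 ± 0.56) and the lipid droplet protein Plin4 (-2.55 ± 0.54). Ucp1, the uncoupling protein of brown fat, stood at 6.30 ± 1.95 (SD, n = 2) in bone marrow-derived and 5.63 ± 1.13 (SD, n = 2) in white arrays (adjusted p = 0.673). The brown adipocyte list had 6 of 21 members lower and 1, Prdm16, higher (1.36), over all genes and when adjusted over the list alone, with a median of -1.59 (camera adjusted p = 0.0159, adjusted p = 0.556 with an estimated correlation). Without the LacZ array its median was -0.38 and its call was lost (camera adjusted p = 0.0908).

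**Figure D1:**
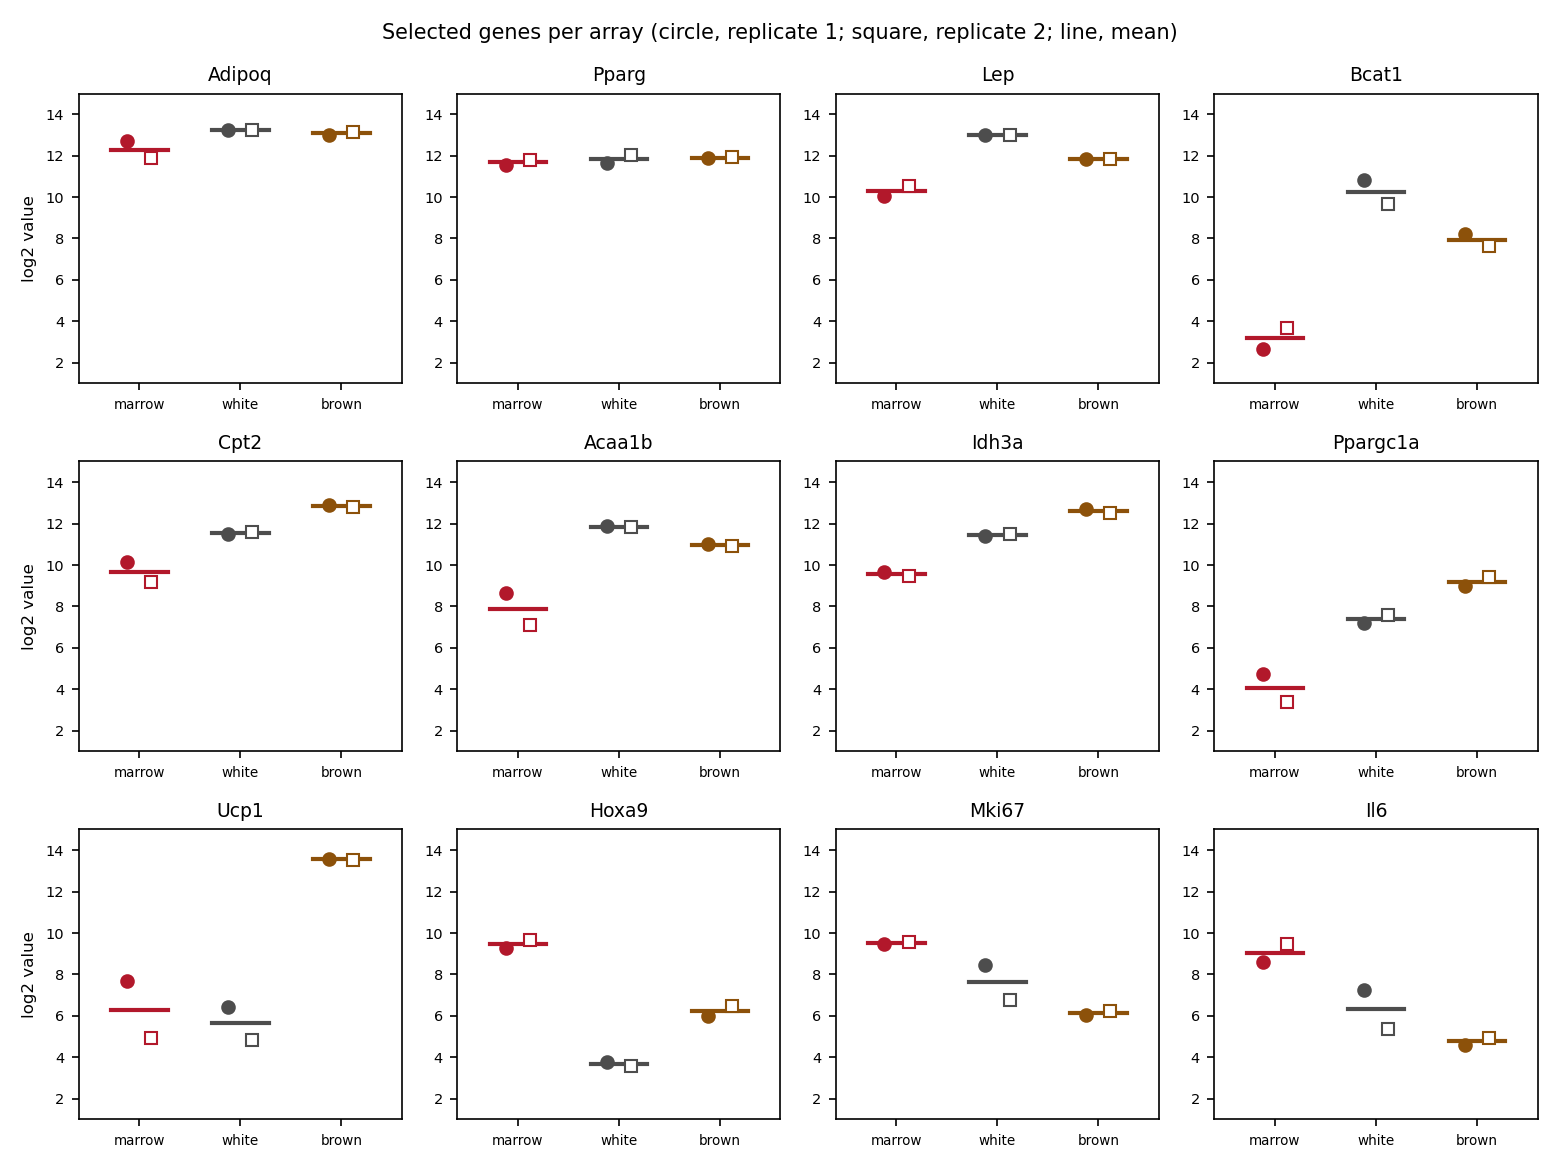
Log2 values of 12 genes on each array (y axis, log2 expression) for bone marrow-derived, gonadal white and brown adipocytes, with a circle for replicate 1, a square for replicate 2 and a line at the mean of 2 arrays. Pparg values sit close together in the 3 groups, and Adipoq is lowest on the LacZ array (11.86, against 13.01 to 13.24 on the white and brown arrays). Bcat1 and Ppargc1a are lowest in the bone marrow-derived arrays, and Ucp1 is high in the brown arrays.

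All 12 endothelial markers were higher in bone marrow-derived than in white adipocytes, over all genes and when adjusted over the list alone, with a median log2 difference of 3.56 (camera adjusted p = 5.07e-09, adjusted p = 0.556 with an estimated correlation). The angiopoietin receptor family member Tie1 was 24.3-fold higher (4.60 ± 0.52), the endothelial cadherin Cdh5 22.8-fold higher (4.51 ± 0.45) and Pecam1 18.6-fold higher (4.22 ± 0.50). Of 8 smooth muscle and pericyte markers 3 were higher, which were Myh11 (3.93 ± 0.34), Tagln (2.33 ± 0.37) and Rgs5 (2.06 ± 0.34), and 3 passed when adjusted over the list alone (camera adjusted p = 0.128). Of 14 preadipocyte and fibroblast markers 3 were higher, Postn (3.59 ± 0.47), Thy1 (3.25 ± 0.34) and Pdgfrb (3.15 ± 0.53), and 1 lower, with the same counts when adjusted over the list alone (camera adjusted p = 0.064). Hematopoietic progenitor markers were higher in 5 of 11 members and lower in 1, with the same counts when adjusted over the list alone (camera adjusted p = 0.0624). These included Tal1 (3.79 ± 0.62), Kit (3.65 ± 0.54) and Gata2 (3.49 ± 0.42), transcription factors and a receptor that endothelial cells also express.

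No macrophage marker passed between bone marrow-derived and white arrays. Of 26 members 0 passed limma's test over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05, with a median of -0.72 (camera adjusted p = 0.26). Ptprc, the pan-leukocyte antigen CD45, stood at 9.24 ± 2.30 (SD, n = 2) in bone marrow-derived and 9.85 ± 1.48 (SD, n = 2) in white arrays. The differences were -0.10 ± 0.79 for the macrophage growth factor receptor Csf1r, -0.50 ± 1.30 for the macrophage antigen Adgre1 and -1.04 ± 1.01 for Cd68. The largest was in the lectin receptor gene Clec4d, at -3.12 ± 1.71 (adjusted p = 0.246). The mean over this list was 10.9 on the GFP array and 8.14 on the LacZ array, so the comparison turned with the array used: the median was 0.71 without the LacZ array (camera adjusted p = 0.0328) and -2.21 without the GFP array (1.28e-05). It was -1.52 without white replicate 2 (0.011). Inflammatory mediators as a list did not pass, with a median and a mean of -0.18 while camera ranked the list upward (adjusted p = 0.87), and with 4 of 29 members higher and 1 lower (2 higher and 1 lower when adjusted over the list alone). This list too turned with the array used and was called either way, with a median of -0.996 without the GFP array (camera adjusted p = 0.0312) and 0.70 without the LacZ array (0.0209). The cytokine Il6 was 6.51-fold higher (2.70 ± 0.66, adjusted p = 0.0359), the inducible nitric oxide synthase Nos2 5.11-fold higher (2.35 ± 0.31, adjusted p = 0.00773) and the acute-phase protein Lcn2 17.2-fold lower (-4.10 ± 0.58, adjusted p = 0.00908).

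The Hox list held the largest rises after Xist. Of 25 Hox genes 12 were higher and 3 lower (16 and 4 when adjusted over the list alone), with a median of 1.32 (camera adjusted p = 0.000308, adjusted p = 0.556 with an estimated correlation). Hoxd10 was 71.5-fold higher (6.16 ± 0.31), Hoxa9 54.9-fold higher (5.78 ± 0.25) and Hoxa10 17.2-fold higher (4.10 ± 0.21), while the 3 lower members, Hoxc8 (-3.41), Hoxc5 (-3.40) and Hoxc4 (-2.06), are all of the Hoxc cluster. These 3 genes, Cox7c, Apln and Prdm16 stand outside the naming rule and were chosen after their values were seen. The immediate early and heat shock list was higher in 4 of 20 members, with 4 when adjusted over the list alone and a median of 0.57 (camera adjusted p = 0.000163, adjusted p = 0.556 with an estimated correlation). The inducible chaperones Hspa1a (2.71 ± 0.51) and Hspa1b (2.56 ± 0.34) led it, with Hspb1 at 1.43 ± 0.30. The cell cycle list had 1 of 15 members higher, the replication factor Mcm2 (1.16 ± 0.32), 0 when adjusted over the list alone, and a median of 1.24 (camera adjusted p = 0.00181, adjusted p = 0.556 with an estimated correlation). Other genes with the largest rises were Ccm2l (5.53 ± 0.62), Clca2 (5.29 ± 0.61), Pcdh17 (5.13 ± 0.55), Klhl4 (5.10 ± 0.40) and the nuclear receptor Nr5a2 (5.08 ± 0.39). Among the lowest were Tph2 (-6.84 ± 0.77), the muscle-type AMP kinase subunit Prkag3 (-5.72 ± 0.32), Crtac1 (-5.59 ± 0.34), Prr32 (-5.54 ± 0.64), Ccn5 (-5.47 ± 0.31) and Mal2 (-5.32 ± 0.34).

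The glycolysis list had 6 of 13 members lower and 2 higher (7 and 2 when adjusted over the list alone, camera adjusted p = 0.058, fry adjusted p = 0.00376). Camera called it without the GFP array (adjusted p = 0.04998), without the LacZ array (0.0442) and without white replicate 2 (0.037). Members include the insulin-responsive hexokinase Hk2, lower (-3.29 ± 0.49), Tpi1, lower (-1.84 ± 0.16), and Hk1, higher (1.74 ± 0.26). The neutrophil list had 1 of 11 members lower, Elane (-1.56 ± 0.40), and 0 when adjusted over the list alone. The T and NK cell list had 1 of 13 higher, Cd247 (3.35 ± 0.63), and 1 when adjusted over the list alone. Of 7 erythroid markers Alas2 was higher (2.48 ± 0.48) and Car1 lower (-3.47 ± 0.54). Of 13 skeletal muscle markers Mylpf was higher (2.48 ± 0.63), while Acta1 (-3.39 ± 0.87) and Pvalb (-3.30 ± 0.85) were lower. The counts of the erythroid and muscle lists were the same when adjusted over the list alone. None of 10 B cell markers or 8 mesothelial markers passed limma's test, where 2 and 1 had an unadjusted p under 0.05. Camera did not call any of these 6 marker lists, with adjusted p = 0.164 for neutrophils, 0.184 for T and NK cells, 0.327 for B cells, 0.839 for erythroid cells, 0.664 for skeletal muscle and 0.506 for mesothelium. Of these, 4 were called with 1 bone marrow-derived array left out. Without the GFP array neutrophil markers had a median of -0.91 (adjusted p = 0.00942) and mesothelial markers of -1.18 (0.00194), against -0.40 and -0.41 with both arrays. Without the LacZ array T and NK cell markers had a median of 0.68 (0.00265) and B cell markers of 0.88 (0.0144), against 0.28 and 0.60.

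The counts of this comparison depended on the white arrays and on the shared estimate of the spread. Limma called 899 higher and 850 lower without white replicate 2, 1577 lower without white replicate 1, 1355 and 1372 without either brown array, and 254 and 301 in an ordinary linear model without moderation. After centring each array on its median the median over all genes moved by -0.168, and 36.6% of the calls were higher, against 47.4% with the deposited scaling. Fry, which tests each list by itself, did not call the brown adipocyte, lipogenesis, heat shock and cell cycle lists (adjusted p = 0.0747, 0.137, 0.0526 and 0.217), and it called mitochondrial biogenesis (0.0349). Camera also called smooth muscle markers without the GFP array (0.0279), progenitor markers without the LacZ array (0.00978) or white replicate 1 (0.0223), and mitochondrial biogenesis without white replicate 1 (0.0481). Fibroblast markers were called without the LacZ array (0.0439), white replicate 1 (0.00462) or either brown array (0.0417). After median centring progenitor (0.0184) and fibroblast (0.0302) markers were called too. Called medians moved over 1.5 times without the LacZ array for adipocyte identity (-0.75), adipokines (-0.79) and lipogenesis (-0.69), and without the GFP array for adipokines (-2.43). Without white replicate 2 they moved for adipokines (-2.16), heat shock (0.35) and cell cycle (0.45), and without white replicate 1 for brown adipocyte genes (-0.90). Among the 13 lists that were not called, 11 moved as much or turned with some array left out.

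**Figure D2:**
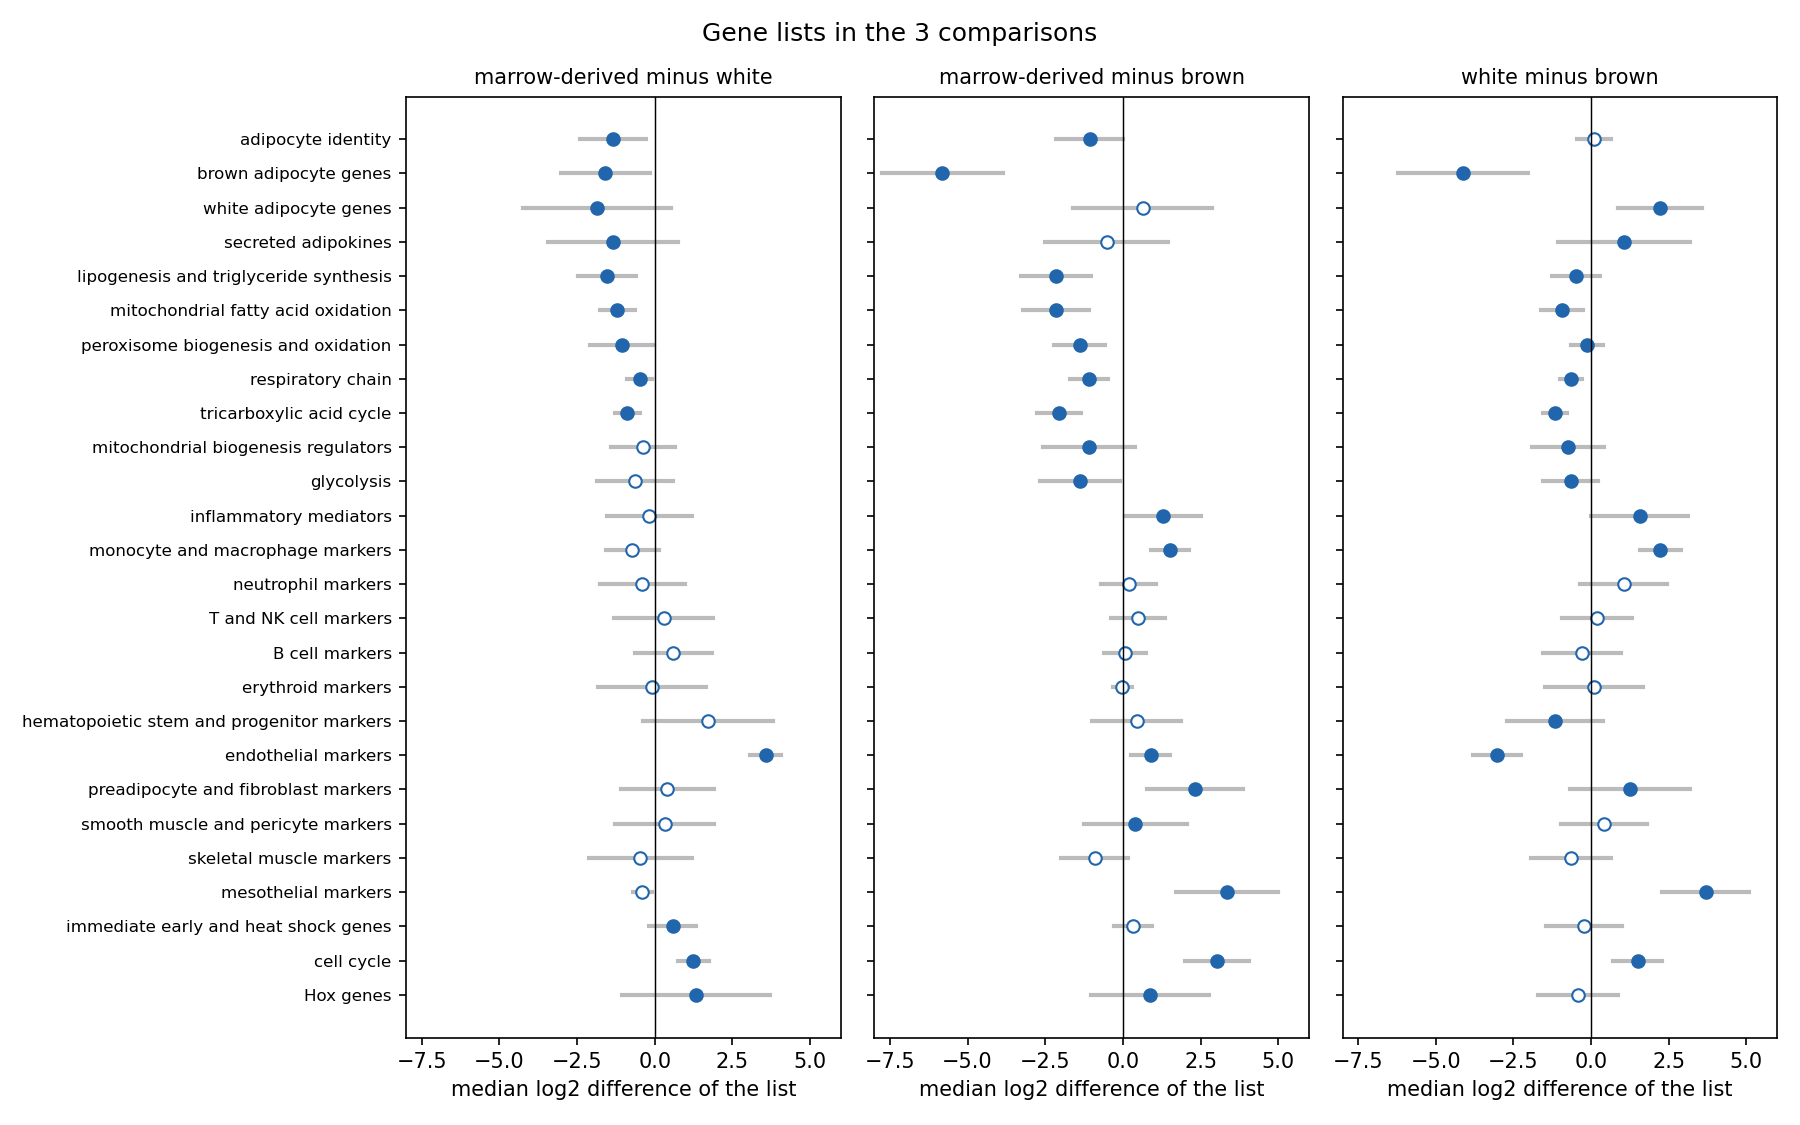
Median log2 difference of each of 26 gene lists (x axis, log2) in the 3 comparisons, with grey lines for 1 SD of the list's members on either side and filled points where camera with its preset correlation passed the threshold of 0.05. Oxidation lists lie left of 0 and endothelial markers right of 0 (median 3.56) in bone marrow-derived against white, and brown adipocyte genes lie farthest left (median -5.82) in bone marrow-derived against brown.

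Against brown arrays, the bone marrow-derived arrays had lower values for the thermogenic program and for all 4 mitochondrial gene lists. Ucp1 was 152-fold lower (-7.25 ± 0.98, adjusted p = 0.0101) and 19 of 21 brown adipocyte genes were lower and 0 higher (20 lower when adjusted over the list alone), with a median of -5.82 (camera adjusted p = 2.16e-14, adjusted p = 0.402 with an estimated correlation). Slc27a2, a fatty acid transporter and acyl-CoA synthetase, was 211-fold lower (-7.72 ± 0.24, adjusted p = 0.000945) and the neurotrophin receptor Ntrk3 172-fold lower (-7.43 ± 0.31, adjusted p = 0.00174). Other genes near the bottom were Ptgds (-7.26 ± 0.82), Otop1 (-7.24 ± 1.26), the fatty acid binding protein Fabp3 (-7.15 ± 0.97), Plet1os (-7.12 ± 0.34) and the lipid droplet gene Cidea (-7.05 ± 1.57). In this comparison 1543 genes were higher and 2068 lower in bone marrow-derived adipocytes, 1163 and 1647 of them at least 2-fold.

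All 15 tricarboxylic acid cycle genes were lower, over all genes and when adjusted over the list alone, with a median of -2.05 (camera adjusted p = 2.00e-12, adjusted p = 0.42 with an estimated correlation). The largest differences were in Dlat (-3.33 ± 0.21), Idh3a (-3.04 ± 0.17) and Dld (-2.80 ± 0.19). Of 19 fatty acid oxidation genes 18 were lower and 1, the non-muscle Cpt1a, was higher (1.22, chosen after its value was seen), with the same counts when adjusted over the list alone. The median was -2.15 (camera adjusted p = 1.55e-11, adjusted p = 0.42 with an estimated correlation), with Hadha (-3.30 ± 0.19), Cpt2 (-3.18 ± 0.33) and Acads (-2.72 ± 0.23) lowest. In the respiratory chain 41 of 50 members were lower and 0 higher (46 lower when adjusted over the list alone), with a median of -1.09 (camera adjusted p = 3.51e-19, adjusted p = 0.427 with an estimated correlation). Examples are Ndufa10 (-2.43 ± 0.17), Uqcrfs1 (-2.40 ± 0.21) and Uqcrq (-2.27 ± 0.23). Peroxisomal genes were lower in 24 of 28 members and higher in 0 (27 lower when adjusted over the list alone), with a median of -1.39 (camera adjusted p = 2.65e-13, adjusted p = 0.42 with an estimated correlation). Acaa1b (-3.11 ± 0.51), Ehhadh (-3.10 ± 0.23) and Phyh (-2.78 ± 0.40) differed most. Mitochondrial biogenesis regulators were lower in 13 of 18 members and higher in 0 (14 lower when adjusted over the list alone), with a median of -1.08 (camera adjusted p = 2.34e-08, adjusted p = 0.42 with an estimated correlation). Ppargc1a was 35.2-fold lower (-5.14 ± 0.47), Perm1 15.4-fold lower (-3.95 ± 0.34) and Ppargc1b 12.7-fold lower (-3.67 ± 0.19).

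Genes of lipogenesis, glycolysis and adipocyte identity were also lower. The lipogenesis list had 14 of 20 members lower and 0 higher (19 lower when adjusted over the list alone), with a median of -2.15 (camera adjusted p = 1.61e-07, adjusted p = 0.46 with an estimated correlation), among them Mlxipl (-4.68 ± 0.60), the elongase Elovl6 (-4.05 ± 0.97) and Slc25a1 (-3.45 ± 0.50). Glycolysis had 9 of 13 members lower and 0 higher, with 9 when adjusted over the list alone and a median of -1.37 (camera adjusted p = 0.000137, adjusted p = 0.402 with an estimated correlation). Examples are Hk2 (-4.01 ± 0.49), Pfkl (-3.22 ± 0.19) and Tpi1 (-1.71 ± 0.16). Of 15 adipocyte identity genes 4 were lower and 0 higher (6 lower when adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.00253, adjusted p = 0.52 with an estimated correlation). Gpd1 (-3.51 ± 0.56), the insulin-responsive glucose transporter Slc2a4 (-2.65 ± 0.23) and the hormone-sensitive lipase Lipe (-1.73 ± 0.23) were the largest. Adipoq (-0.80 ± 0.30, adjusted p = 0.123) and Pparg (-0.22 ± 0.20, adjusted p = 0.478) did not pass, and Lep was 2.89-fold lower (-1.53 ± 0.21, adjusted p = 0.0101). The adipokine list had 3 of 11 members lower, Nrg4 (-4.40 ± 0.67), Nampt (-2.05 ± 0.18) and Lep, and 1 higher, Apln (2.57 ± 0.63), with the same counts when adjusted over the list alone (camera adjusted p = 0.15).

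Cell cycle, stromal and mesothelial genes were higher than in brown adipocytes. Of 15 cell cycle genes 13 were higher and 0 lower (14 higher when adjusted over the list alone), with a median of 3.03 (camera adjusted p = 3.09e-07, adjusted p = 0.46 with an estimated correlation). The topoisomerase Top2a was 12.2-fold higher (3.61 ± 0.53), the apoptosis inhibitor Birc5 followed (3.46 ± 0.64), and the proliferation marker Mki67 was 10.5-fold higher (3.39 ± 0.54). Of 8 mesothelial markers 5 were higher (7 when adjusted over the list alone), with a median of 3.35 (camera adjusted p = 0.000129, adjusted p = 0.46 with an estimated correlation). Examples are Upk3b (5.39 ± 0.68), Krt19 (4.68 ± 0.58) and Bnc1 (4.09 ± 0.71). Fibroblast markers were higher in 6 of 14 members and lower in 1 (11 and 1 when adjusted over the list alone), with a median of 2.31 (camera adjusted p = 4.76e-05, adjusted p = 0.42 with an estimated correlation). The matrix genes Dcn (3.83 ± 0.70) and Mfap5 (3.83 ± 0.59) and the surface antigen Thy1 (3.70 ± 0.34) led them. Smooth muscle markers were higher in 3 of 8 members, Tagln (3.69 ± 0.37), Myh11 (3.58 ± 0.34) and Acta2 (2.61 ± 0.39), with 3 when adjusted over the list alone and a median of 0.40 (camera adjusted p = 0.0153, adjusted p = 0.52 with an estimated correlation). Of 12 endothelial markers 2 were higher, Vwf (2.54 ± 0.46) and Erg (1.40 ± 0.31), with 2 when adjusted over the list alone and a median of 0.89 (camera adjusted p = 0.00713, adjusted p = 0.651 with an estimated correlation). Hox genes were higher in 8 of 25 members and lower in 3 (10 and 4 when adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.0146, adjusted p = 0.623 with an estimated correlation). The largest differences were in Hoxd10 (5.02 ± 0.31), Hoxa10 (4.53 ± 0.21) and Hoxc10 (4.26 ± 0.35). Without the LacZ array the endothelial, smooth muscle and Hox lists lost their calls (camera adjusted p = 0.0602, 0.0666 and 0.0666).

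Macrophage and inflammatory genes were higher in bone marrow-derived than in brown arrays as lists, while the other leukocyte lists did not pass. Of 26 macrophage markers 0 passed limma's test, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. The median was 1.51 (camera adjusted p = 0.00713, adjusted p = 0.684 with an estimated correlation), and it was -0.04 without the GFP array. The call was also lost without brown replicate 2 (camera adjusted p = 0.0557). Ptprc differed by 1.41 ± 1.23, Csf1r by 1.78 ± 0.79, Adgre1 by 2.11 ± 1.30 and Cd68 by 1.61 ± 1.01, and these 4 genes did not pass the test. Inflammatory mediators had 2 of 29 members higher, Il6 (4.26 ± 0.66) and Nos2 (1.36 ± 0.31), with 1 when adjusted over the list alone and a median of 1.30 (camera adjusted p = 0.00138, adjusted p = 0.584 with an estimated correlation). Without the GFP array that call was lost (camera adjusted p = 0.0888). The white adipocyte list had 3 of 12 members higher, Tcf21 (4.66 ± 0.75), Hoxc10 and the mesothelial transcription factor Wt1 (2.58 ± 0.57), and 3 lower (5 and 4 when adjusted over the list alone, camera adjusted p = 0.548). The immediate early and heat shock list was higher in 2 of 20 members, Ier3 (1.06 ± 0.16) and Egr2 (0.97 ± 0.24), with 1 when adjusted over the list alone (camera adjusted p = 0.0526). Of 11 progenitor markers 1, Hlf, was lower (-3.52 ± 0.17), with 1 when adjusted over the list alone (camera adjusted p = 0.53). None of the neutrophil, T and NK cell, B cell, erythroid and skeletal muscle markers passed limma's test, where 1, 1, 0, 0 and 2 members had an unadjusted p under 0.05. Camera did not call these 5 lists, with adjusted p = 0.929, 0.137, 0.779, 0.788 and 0.124. Without the LacZ array it called T and NK cell markers (median 0.88, adjusted p = 0.00106) and B cell markers (0.56, 0.0494). Skeletal muscle markers averaged 6.71 on brown replicate 1 and 4.63 on brown replicate 2, and without replicate 2 their median moved from -0.91 to -1.96 and was called (adjusted p = 1.70e-06). Other genes with the largest rises were Ptchd4 (5.63 ± 0.47), Clca2 (5.52 ± 0.61), the mechanosensitive channel Piezo2 (5.21 ± 0.33), Uchl1 (4.79 ± 0.74) and Igfbp6 (4.71 ± 0.81).

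The count of genes in this comparison rested on both brown arrays, which were the most alike. Limma called 121 higher and 355 lower without brown replicate 1, 61 and 239 without brown replicate 2, and 296 and 665 without moderation. Median centring moved the median over all genes by -0.194 and gave 1006 higher genes and 28.5% of the calls higher, against 42.7%, and the macrophage covariate, chosen after seeing the data, gave 974 higher. Fry did not call the adipocyte identity, lipogenesis, inflammatory, macrophage and endothelial lists (adjusted p = 0.0576, 0.051, 0.20, 0.439 and 0.222). It also left out smooth muscle, mesothelium and cell cycle (each 0.051) and Hox genes (0.0576). Without the GFP array the adipokine median moved from -0.52 to -0.96. Camera called the mixed immediate early and heat shock list higher after cyclic loess (median 0.46, adjusted p = 0.0124). The median of that list was 0.32 with all arrays, 0.47 without the GFP array and 0.49 without brown replicate 1. Of its 20 members 17 were above 0, but the inducible chaperone Hspa1a was the lowest, at -1.63. Called medians moved over 1.5 times without the LacZ array for adipocyte identity (-0.39), lipogenesis (-1.36), Hox genes (0.36), inflammatory mediators (2.32) and macrophage markers (2.90). Without the GFP array they moved for adipocyte identity (-1.75), smooth muscle (0.64) and inflammatory mediators (0.48). Among the 9 lists that were not called, 8 moved as much or turned.

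**Figure D3:**
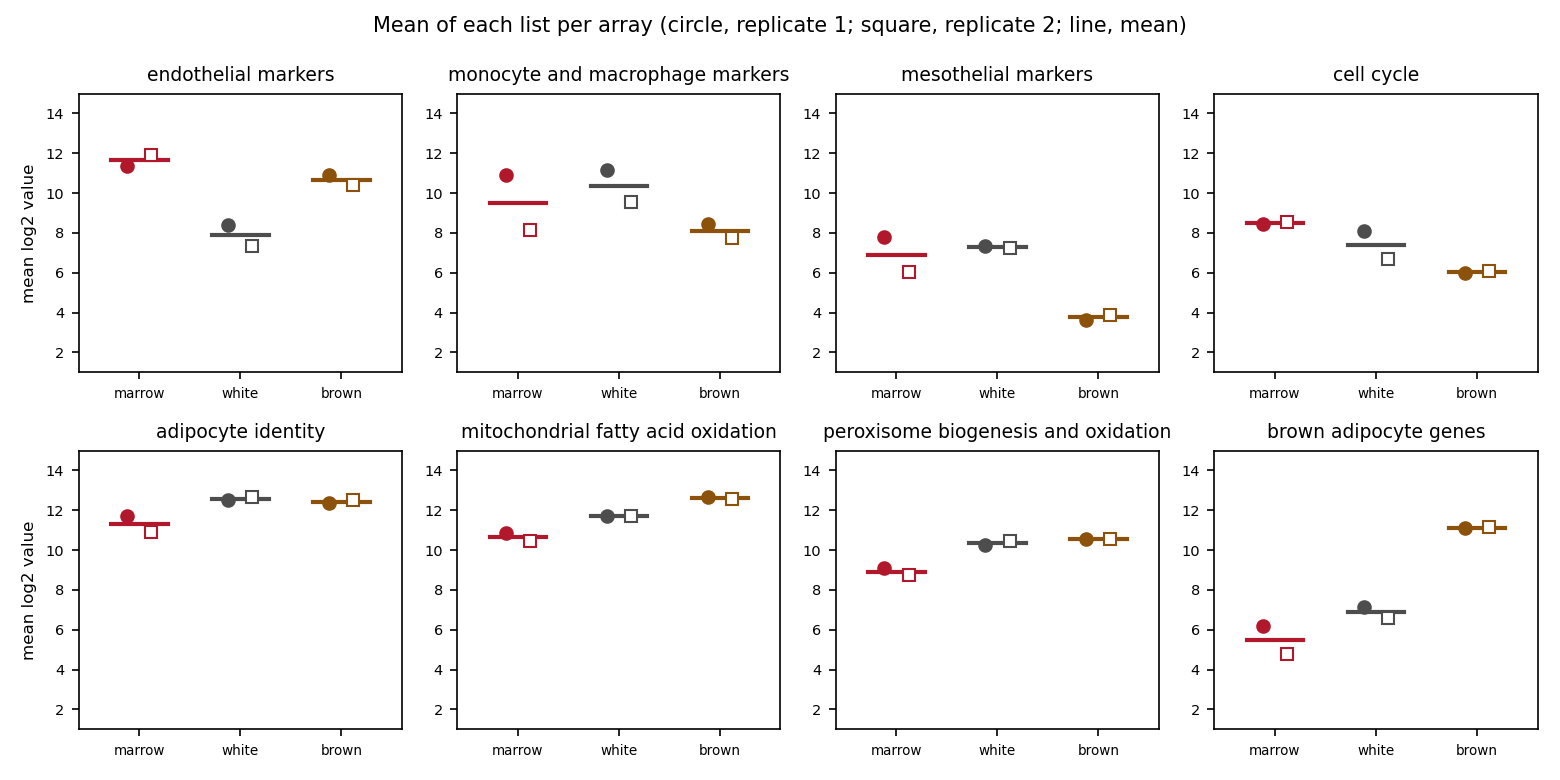
Mean log2 value of 8 gene lists on each array (y axis, mean log2 expression) for bone marrow-derived, gonadal white and brown adipocytes, with a circle for replicate 1, a square for replicate 2 and a line at the mean of 2 arrays. The endothelial mean is lowest in the 2 white arrays (8.40 and 7.35), and the macrophage mean is higher on replicate 1 than on replicate 2 in each of the 3 groups.

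White and brown adipocytes differed in the genes that define them. Ucp1 was 242-fold lower in white than in brown adipocytes (-7.92 ± 0.98, adjusted p = 0.0148), and 13 of 21 brown adipocyte genes were lower and 0 higher (21 lower when adjusted over the list alone), with a median of -4.13 (camera adjusted p = 1.15e-15, adjusted p = 0.33 with an estimated correlation). Slc27a2 (-7.98 ± 0.24, adjusted p = 0.00137), the elongase Elovl3 (-7.31 ± 0.61), Plet1os (-6.74 ± 0.34), the neuropeptide gene Nts (-6.68 ± 0.80), Fabp3 (-6.48 ± 0.97), Lgr6 (-6.32 ± 0.19) and Cpn2 (-6.13 ± 0.36) were the other lowest genes. Of 12 white adipocyte genes 8 were higher and 0 lower (11 higher when adjusted over the list alone), with a median of 2.22 (camera adjusted p = 1.54e-07, adjusted p = 0.312 with an estimated correlation). Examples are Agt (5.65 ± 0.71), the imprinted gene Mest (2.71 ± 0.42) and Hoxc8 (2.56 ± 0.21). Lep was 2.20-fold higher (1.14 ± 0.21, adjusted p = 0.0338). Adipoq (0.15 ± 0.30) and Pparg (-0.09 ± 0.20) did not pass. Of 15 adipocyte identity genes 0 passed limma's test, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05, with Retn at 1.11 ± 0.57 the largest difference (camera adjusted p = 0.80). In all, 686 genes were higher and 946 lower in white, 626 and 832 of them at least 2-fold.

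Mitochondrial genes were lower in white than in brown adipocytes. The respiratory chain had 18 of 50 members lower and 0 higher (35 lower when adjusted over the list alone), with a median of -0.64 (camera adjusted p = 1.78e-16, adjusted p = 0.397 with an estimated correlation). Examples are Ndufs1 (-1.45 ± 0.19), Cyc1 (-1.44 ± 0.20) and Uqcrc1 (-1.37 ± 0.16). The tricarboxylic acid cycle had 11 of 15 lower and 0 higher (15 lower when adjusted over the list alone), with a median of -1.17 (camera adjusted p = 1.50e-10, adjusted p = 0.397 with an estimated correlation). The largest differences were in Dlat (-1.85 ± 0.21), Ogdh (-1.63 ± 0.19) and Suclg1 (-1.48 ± 0.19). Fatty acid oxidation had 7 of 19 lower and 1, Cpt1a (chosen after its value was seen), higher (1.20), or 14 and 1 when adjusted over the list alone, with a median of -0.94 (camera adjusted p = 4.21e-08, adjusted p = 0.397 with an estimated correlation). Hadha (-2.07 ± 0.19), Acadvl (-1.61 ± 0.27) and Etfdh (-1.34 ± 0.16) were lowest. Biogenesis regulators were lower in 6 of 18 and higher in 0 (12 lower when adjusted over the list alone), with a median of -0.75 (camera adjusted p = 1.36e-08, adjusted p = 0.33 with an estimated correlation), among them Perm1 (-4.87 ± 0.34), Ppargc1b (-3.02 ± 0.19) and Sirt3 (-1.61 ± 0.20), while Ppargc1a did not pass (-1.82 ± 0.47, adjusted p = 0.0757). Glycolysis had 4 of 13 lower and 0 higher (7 lower when adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.00325, adjusted p = 0.33 with an estimated correlation). Examples are Pfkl (-2.14 ± 0.19), Pfkm (-1.78 ± 0.37) and Hk1 (-1.64 ± 0.26). Peroxisomal genes shifted little: 2 of 28 were lower, Amacr (-1.46 ± 0.23) and Pex6 (-1.06 ± 0.21), with 2 when adjusted over the list alone and a median of -0.14 (camera adjusted p = 0.0478, adjusted p = 0.654 with an estimated correlation). Of 20 lipogenic genes 1, Acacb, was lower (-2.59 ± 0.47), with 1 when adjusted over the list alone and a median of -0.49 (camera adjusted p = 0.0102, adjusted p = 0.654 with an estimated correlation). The peroxisome list lost its call without white replicate 1 (camera adjusted p = 0.295), without brown replicate 2 (0.0999), without either bone marrow-derived array (0.0533) and after median centring (0.0531). Without white replicate 1 the lipogenic list lost its call too (camera adjusted p = 0.068), as it did without brown replicate 2 (camera adjusted p = 0.0546).

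Marker lists of other cell types differed as well. Endothelial markers were lower in white arrays in 10 of 12 members and higher in 0 (11 lower when adjusted over the list alone), with a median of -3.02 (camera adjusted p = 2.58e-09, adjusted p = 0.397 with an estimated correlation). Examples are Tie1 (-3.67 ± 0.52), Emcn (-3.39 ± 0.46) and the VEGF receptor Kdr (-3.18 ± 0.34). Progenitor markers were lower in 4 of 11 members and higher in 0 (5 lower and 1 higher when adjusted over the list alone), with a median of -1.17 (camera adjusted p = 0.0111, adjusted p = 0.433 with an estimated correlation). They included Gata2 (-3.33 ± 0.42), Tal1 (-3.15 ± 0.62) and Mecom (-2.44 ± 0.36), and the list lost its call without white replicate 2 (camera adjusted p = 0.052). Mesothelial markers were higher in 6 of 8 members (7 when adjusted over the list alone), with a median of 3.69 (camera adjusted p = 1.87e-06, adjusted p = 0.397 with an estimated correlation). Examples are Upk3b (5.35 ± 0.68), Krt19 (4.88 ± 0.58) and Gpm6a (4.38 ± 0.67). Fibroblast markers were higher in 5 of 14 members and lower in 1 (6 and 1 when adjusted over the list alone), with a median of 1.27 (camera adjusted p = 0.00486, adjusted p = 0.468 with an estimated correlation), among them Dcn (3.58 ± 0.70), Mfap5 (3.55 ± 0.59) and Col1a2 (3.28 ± 0.38). Their call was lost without white replicate 1 (camera adjusted p = 0.0749). Macrophage markers had a median of 2.23 (camera adjusted p = 8.49e-06, adjusted p = 0.595 with an estimated correlation), although 0 of 26 passed limma's test over all genes or when adjusted over the list alone and 6 had an unadjusted p under 0.05. Ptprc differed by 2.01 ± 1.23, Csf1r by 1.88 ± 0.79, Adgre1 by 2.61 ± 1.30, Cd68 by 2.66 ± 1.01 and the lipid-associated macrophage receptor Trem2 by 3.66 ± 1.27.

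The adipokine list had 3 of 11 members higher, Agt, Sfrp5 (4.89 ± 0.47) and Lep, and 1 lower (4 and 1 when adjusted over the list alone), with a median of 1.06 (camera adjusted p = 0.025, adjusted p = 0.397 with an estimated correlation). Inflammatory mediators had 1 of 29 higher, Lcn2 (4.55 ± 0.58), with 1 when adjusted over the list alone and a median of 1.56 (camera adjusted p = 0.000973, adjusted p = 0.56 with an estimated correlation). That call was lost without white replicate 1 (camera adjusted p = 0.0785). The cell cycle list had 1 of 15 higher, Aurkb (2.41 ± 0.46), and 3 when adjusted over the list alone, with a median of 1.50 (camera adjusted p = 0.000132, adjusted p = 0.56 with an estimated correlation). The immediate early and heat shock list was lower in 2 of 20 members, Hspa1a (-4.34 ± 0.51) and Hspa1b (-3.55 ± 0.34), with 2 when adjusted over the list alone (camera adjusted p = 0.0616). Of 25 Hox genes 2 were higher, Hoxc8 and Hoxc9 (2.55 ± 0.47), and 5 lower, led by Hoxa9 (-2.55 ± 0.25), or 2 and 8 when adjusted over the list alone (camera adjusted p = 0.0682). Smooth muscle markers split, with Acta2 higher (2.68 ± 0.39) and Rgs5 lower (-1.88 ± 0.34), or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.359), and of 7 erythroid markers Car1 was higher (2.94 ± 0.54) and Alas2 lower (-2.50 ± 0.48), over all genes and when adjusted over the list alone (camera adjusted p = 0.829). None of the neutrophil, T and NK cell, B cell and skeletal muscle markers passed limma's test, where 4, 2, 2 and 2 members had an unadjusted p under 0.05, and camera did not call these lists (adjusted p = 0.0682, 0.829, 0.512 and 0.351). Without brown replicate 2, the array with fewer muscle transcripts, the skeletal muscle median moved from -0.66 to -1.65 and was called (adjusted p = 3.22e-05), and without either bone marrow-derived array the neutrophil list was called (0.0367). Other genes with the largest rises were Upk3b, Ccn5 (5.31 ± 0.31), the protease inhibitor Timp1 (5.00 ± 0.50), the oxytocin receptor Oxtr (4.98 ± 0.51), Ptchd4 (4.97 ± 0.47), the complement component C6 (4.89 ± 0.58) and Sfrp5.

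The calls between white and brown adipocytes nearly vanished without a brown array and were fewer without a white array. Limma called 0 higher and 7 lower without brown replicate 1 (2784 at an unadjusted p under 0.05), 0 and 5 without brown replicate 2 (3232), 321 and 516 without white replicate 1, 391 and 341 without white replicate 2, and 0 and 0 without moderation (3880). With the macrophage covariate, chosen after seeing the data, it called 140 higher and 112 lower, and with only these 4 arrays or without either bone marrow-derived array 1036 higher. Fry did not call the lipogenesis, peroxisome, inflammatory, macrophage, fibroblast and cell cycle lists (adjusted p = 0.361, 0.247, 0.219, 0.268, 0.0539 and 0.219). Camera called the immediate early and heat shock list without either bone marrow-derived array (median -0.22), white replicate 1 (-0.32) or brown replicate 2 (-0.34). It called Hox genes without either bone marrow-derived array (median -0.42) or white replicate 2 (-0.49). Called medians moved over 1.5 times without white replicate 1 for cell cycle (0.66), macrophage (1.47), inflammatory (0.69) and peroxisome (-0.01) genes. Without white replicate 2 they moved for cell cycle (2.35), progenitor (-0.58) and peroxisome (-0.29) genes, and without brown replicate 1 for adipokines (0.61). Among the 9 lists that were not called, 8 moved as much or turned.

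The genes that set bone marrow-derived adipocytes apart from white fat overlapped with those that set them apart from brown fat. A total of 907 genes was higher in both comparisons and 1313 lower, where independent lists of those sizes would share 189 and 281. At an unadjusted p under 0.05, 10.9% of all genes were higher in both and 12.3% lower in both, against averages of 0.642% and 0.667% over 50 simulated data sets of unchanged groups in which both comparisons shared an arm. No gene was changed in those data sets, so they do not show how much overlap a shared arm that truly differs would give. Another 11 genes were higher than in white and lower than in brown, and 31 lower than in white and higher than in brown. Xist, Clca2, Hoxd10, Hoxa10 and Hoxc10 were higher against both, and Bcat1, Mal2, Lep, Ppargc1a, Nrg4 and Mlxipl lower against both. Both comparisons use the same bone marrow-derived arrays, so part of the excess may come from the shared arrays. Xist was high on both of these arrays and low on all white and brown arrays. A difference in sex would therefore enter both comparisons and could not be told from cell type among the shared genes. With a different one in each comparison, a setting chosen after seeing the data, fewer genes were shared. The GFP array against white and the LacZ array against brown shared 585 higher and 882 lower (117 and 174 for independent lists), and the reverse shared 413 and 911 (142 and 198). The counts in opposite directions were 20 and 35 in the former and 27 and 123 in the latter. Without brown replicate 1 the shared calls were 88 and 234, without brown replicate 2 they were 43 and 144, and without white replicate 2 they were 463 and 487.

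Xist, the RNA that coats the inactive X chromosome, had the largest rise in both comparisons of the bone marrow-derived arrays. It was 206-fold higher than in white (7.69 ± 0.19, adjusted p = 0.00113) and 179-fold higher than in brown adipocytes (7.48 ± 0.19, adjusted p = 0.000849). Its log2 value was 10.87 on the GFP array and 10.85 on the LacZ array, against 2.99 to 3.39 on the 4 white and brown arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty, chosen after their values were seen, were 9.15, 7.28 and 5.59 on the GFP array and 5.35, 3.97 and 2.81 on the LacZ array. They were 10.80 to 11.61, 7.34 to 7.88 and 7.25 to 7.53 on the white and brown arrays. Their differences between bone marrow-derived and white arrays did not pass the test: Eif2s3y was at -3.86 ± 1.19 (adjusted p = 0.0697), Kdm5d at -1.91 ± 1.03 (adjusted p = 0.243) and Uty at -3.14 ± 0.87 (adjusted p = 0.0515).

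**Figure D4:**
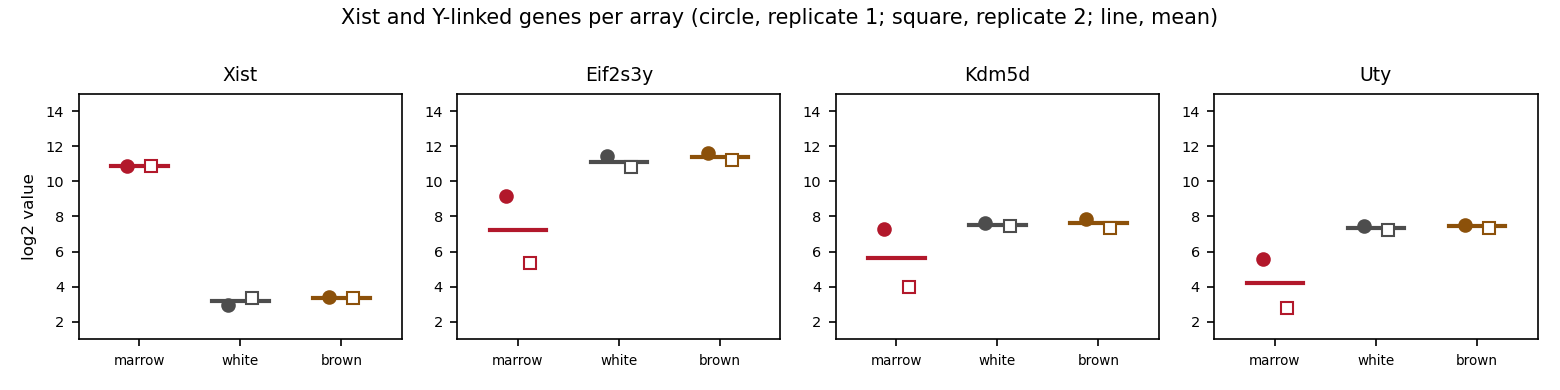
Log2 values of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each array (y axis, log2 expression), with a circle for replicate 1, a square for replicate 2 and a line at the mean of 2 arrays per group. Xist is above 10 on both bone marrow-derived arrays and below 4 elsewhere, and the LacZ array (square) has the lowest Y-linked values.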

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

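The result given here was picked out by a fixed rule, and no test of its cause was chosen after it was seen. Probe sets without a single gene name lay outside the gene comparisons, and there 1049 of 9492 were higher and 457 lower in bone marrow-derived than in white adipocytes. That is 15.9% called, against 24.0% of the named probe sets.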

How the results depend on the processing

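The macrophage covariate, the different bone marrow-derived array per comparison and, for gene lists, median centring were chosen after the data were seen; the other settings were planned. No called gene named by the rule changed direction in any setting. Of the called named genes (74 against white, 66 against brown, 58 white against brown) the ordinary model lost 61, 40 and 58, and the macrophage covariate 4, 6 and 42. Without white replicate 2, 27 of the 74 were lost, and without brown replicate 1 or 2, 40 or 46 of the 66 and 55 of the 58. Counts are given as higher and lower. Bone marrow-derived against white (2170 and 2409): 1355 and 1372 with only the 4 arrays, 254 and 301 in the ordinary model, 4019 and 4325 over every probe set. Bone marrow-derived against brown (1543 and 2068): 296 and 665 in the ordinary model, 1006 higher after median centring, 974 higher with the macrophage covariate, 2754 and 3423 over every probe set. White against brown (686 and 946): 1036 higher with only the 4 arrays, 0 and 0 in the ordinary model (3880 genes at an unadjusted p under 0.05), 1092 higher with array weights, 140 and 112 with the macrophage covariate, 1145 and 1566 over every probe set. Counting every probe set counts more tests; for the other changes the cause was not tested.

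With an array left out, the lone array is assumed to vary like the other groups. The counts then ran from 899 to 2137 higher and 850 to 2144 lower against white, 61 to 1405 and 239 to 1723 against brown, and 0 to 1036 and 5 to 1215 for white against brown. Lists against white ran from 4 to 10 higher and 9 to 14 lower. The macrophage median against white ran from -2.21 to 0.71 and the inflammatory median from -0.996 to 0.70, each turning with the bone marrow-derived array kept. Shared genes (907 and 1313) ran from 43 to 892 higher and 144 to 1176 lower. They were 582 and 782 with only the 4 arrays, 132 and 185 in the ordinary model, 550 higher after median centring and 586 higher with the macrophage covariate. With a different bone marrow-derived array in each comparison they were 585 higher (GFP against white) and 413 higher (LacZ against white). Camera called 0 lists higher and 0 lower with an estimated correlation in each comparison, and fry called 2, 1 and 3 higher. The root mean square differences were 3.23, 2.97 and 2.87 over the 1000 most variable genes and 1.46, 1.33 and 1.17 without dim genes, in the same order.

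The labels share replicate numbers but do not pair the samples, and deviations of same-numbered arrays correlated at 0.205, -0.004 and 0.277. A replicate block gave 1879 and 2149 genes against white, 1279 and 1787 against brown, and 624 and 640 for white against brown. With the block camera also called the macrophage (adjusted p = 0.0296) and fibroblast lists (0.0284) against white and the neutrophil list for white against brown (0.0492). Values near background or the top of the range limit the folds of dim and very abundant genes.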

Other observations

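The tests of the patterns weighed here were chosen after the patterns were seen, apart from the planned cyclic loess. For the second endothelial list and the normalization tests, what each explanation predicts was written down before the values of the test were computed.

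Beyond the genes described above, several genes set the bone marrow-derived arrays apart from both other groups; they were chosen after their values were seen. Higher were the transcription factor Foxf1 (log2 difference 4.76 against white, 4.64 against brown), the leptin receptor Lepr (3.58 and 3.91), and the vascular genes Esm1 (3.96 and 4.65), Angpt2 (4.01 and 3.43) and Plvap (3.33 and 3.10). Lower were Grb14, an inhibitor of insulin receptor signalling (-5.19 and -5.41), and the lipid droplet enzyme Pnpla3 (-4.37 and -4.66).

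The bone marrow-derived arrays also differed from each other, with 1 array per donor marker and no test. The GFP array had 517 genes at least 4-fold higher and 78 lower than the LacZ array, where 309 genes differed that much within the white pair and 48 within the brown pair. The largest gaps, chosen after they were seen, included the lipoxygenase Alox15 (6.81), the acute-phase gene Saa3 (5.18), the chemokine Cxcl13 (5.16), the neutrophil gene S100a9 (5.13), Cd86 of antigen-presenting cells (4.88) and the brown adipocyte gene Cidea (4.87). In the opposite direction lay H60c (-4.26), Scn3a (-4.12) and Foxc2 (-3.73).

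Endothelial genes were higher in bone marrow-derived than in white arrays. Endothelial cells or their RNA in the sorted fraction predict a rise of a second endothelial list, whose median was 3.56 with 18 of 21 genes higher and 0 lower. Against brown arrays its median was only 0.96, with 2 of 21 higher and 0 lower. White against brown gave a median of -2.65, with 17 lower and 0 higher. The list averaged 11.48 in bone marrow-derived, 10.59 in brown and 8.35 in white arrays, so the white arrays stood farthest apart. Floating adipocytes carry attached cells, donor-derived endothelial cells would pass a sort on GFP or LacZ, and Pecam1 (11.4), Cdh5 (11.5) and Tie1 (11.9) were abundant, though expression by the marrow-derived adipocytes themselves predicts the same values. A lower share of adipocyte RNA alone predicts that markers of other cell types rise alike. The endothelial median lay 4.28 above the macrophage median, with an SD of both lists of 0.98. For these lists, that argues against a lower share of adipocyte RNA as the only source. It could still act together with other changes. Macrophage genes were already high in white arrays (mean 10.35, against 7.87 for endothelial genes), but their mean in bone marrow-derived arrays was lower (9.52). The macrophage median against white turned with the array, at 0.71 on the GFP and -2.21 on the LacZ array. The endothelial mean was 11.36 on the GFP and 11.93 on the LacZ array, against 8.40 and 7.35 on the white arrays. Cyclic loess and median centring of the deposited values left an endothelial median of at least 3.40. They start from values that were already normalized, so the original normalization was not tested.

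Oxidation and peroxisome genes were lower in bone marrow-derived than in white arrays. A lower share of adipocyte RNA could not be told from lower expression per adipocyte, since the adipocyte identity median minus the oxidation median was -0.25 with an SD of 1.06. The identity median fell by 0.75 on the GFP and 1.98 on the LacZ array and the oxidation median by 1.08 and 1.21, while Pparg (-0.13) did not pass. Cyclic loess and median centring of the deposited values left the median at -1.06 or lower. They start from values that were already normalized, so the original normalization was not tested.

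Xist was high on both bone marrow-derived arrays, and Y-linked values there lay a median of 1.80 (GFP) and 4.58 (LacZ) below the mean of the 4 other arrays, a difference that did not pass the test gene by gene against white. On the GFP array Kdm5d (7.28) lay close to the 4 other arrays (7.34 to 7.88), while Eif2s3y (9.15) and Uty (5.59) lay farther below them. The Y-linked genes were higher on the GFP than on the LacZ array by a median of 3.30, inside the macrophage range of 1.26 to 4.55, so male leukocytes among female cells on the GFP array could not be excluded. Mesothelial markers (8 of 8 members, median 1.95) and adipocyte identity genes (12 of 15, median 0.84) were also higher on the GFP array. Endothelial markers went the other way (0 of 12 higher, median -0.60). The gap therefore does not single out leukocytes among the cell types that differed between these arrays. The sort on the donor marker would remove host leukocytes without it, and would pass donor-derived ones. Hybridization of X-linked relatives does not account for the gap in Kdm5d and Uty between the GFP and LacZ arrays. Kdm5c and Kdm6a, on the probe sets used, differed by at most 0.25, while Kdm5d differed by 3.30 and Uty by 2.78. Eif2s3x, the relative of Eif2s3y, was not part of that test and stood at 7.41 on the GFP and 7.73 on the LacZ array. The test does not address the Y-linked signal that remained on each array. Over all probe sets of Kdm5c and Kdm6a the GFP minus LacZ difference ran from -0.98 to 0.38. Sex as a source of calls against white adipocytes could not be told from cell type, since 0 white arrays had Xist above 8. The same holds against brown adipocytes, where Xist was 3.39 and 3.36, and for the genes shared by both comparisons.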
